A study of Drosophila melanogaster with 38 samples.

How the data were processed

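Single cells of fly optic lobes were captured with the droplet-based 3' kit version 2 of 10x Genomics, per the labels, in 38 libraries of the Canton S strain. The labels put 5 libraries at P15, 5 at P30, 4 at P40, 4 at P50, 5 at P70 and 15 in the Adult, and the stage was the only factor compared. Reads were processed with bcl2fastq 2.18, Cell Ranger 2.1.1 and Seurat 3, with the genome build BDGP6, per the submitters' processing notes. Filters on cells and the treatment of doublets are not given in the sources used here.

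For each stage, the authors deposited a table of average levels per gene and cluster over the cells of all its libraries, on a natural log scale, per the file headers and the values. Its back-transformed values, exp(value) minus 1, summed to 10000 in every column, so each is the mean normalized count per 10000 counts of a cell and has a true zero. A companion table deposited by the authors gives, per gene and cluster, the probability from 0 to 1 that the gene is ON, from a mixture model over the clusters of that stage, per the file headers and values. The authors' deposited marker tables give per gene and cluster the natural log fold change against the other cells of the stage, per the file headers, with the base taken from the version of Seurat. Those deposited tables also hold the adjusted p-value, with cells as units, and the share of cells in which the gene was detected. No table holds values of single libraries, so no replicate error, no test between stages and no paired analysis could be made, and tables were normalized separately.

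Clusters are named by numbers in every table and have no cell type names. The tables held 216 clusters at P15, 201 at P30, 200 at P40, 202 at P50, 206 at P70 and 199 in the Adult, with 188 at all stages and 231 in any. Genes numbered 11299, 11496, 11099, 11578, 11649 and 12028 in that order, 9903 in all tables and 13306 in any. Of these names 10165 were current symbols of the BDGP6.54 annotation, 2526 were annotation symbols and 476 were synonyms that were translated to the current symbol, 18 mitochondrial names were kept, and 121 had no match and were kept as given. Coordinates are those of BDGP6.54, which is not the build of the authors' reads. A mixture probability was given for 196 clusters at P15, 200 at P30, 199 at P40, 201 at P50, 205 at P70 and 198 in the Adult. A cluster was taken as neuronal where the glial factor repo was OFF and elav was ON, which held for 181, 181, 179, 178, 178 and 179 clusters.

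Depth was not given. A column's smallest value above 0 comes from about 1 count in 1 of its larger cells, averaged over all its cells, so 10000 divided by that value gave an estimate, on the high side, of the counts behind a column. Its medians were 905839 at P15, 1321100 at P30, 863523 at P40, 1096760 at P50, 1314090 at P70 and 2913120 in the Adult, with a minimum of 12087 at P15. The floor used for a level was 3 counts of that estimate, and it covers counting error only.

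The gene lists, thresholds, tests, alternatives and the rule for named genes were fixed before the data were examined. For each pair of stages the difference of the deposited log values was taken in each cluster with a column at both, and the median over clusters was used. A gene was called higher or lower at a median of at least 0.5 ln units with at least 90% of clusters in that direction and a mean level of at least 0.25 ln units at either stage. This size rule stands in place of a test. A list's value is the median over its measured genes, with no level filter, and its percentile among 10000 random lists of the same size drawn from 20 bins of mean level. The lists covered transmitter enzymes and transporters, receptors for acetylcholine and for glutamate, GABA and histamine, synaptic vesicles and active zones, ion channels, axon guidance, dpr and DIP genes, beat and side genes, other adhesion genes, growth cone cytoskeleton and immature neurons, ecdysone response, progenitors and cell cycle, ribosomal proteins, oxidative phosphorylation, the mitochondrial genome, glycolysis, neuropeptides, stress and immediate early genes, cell death, the Wnt pathway, transcription factors and dosage compensation. Further lists held markers of glia, photoreceptors, Kenyon cells, and hemocytes, fat body and muscle.

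Distinctness was the median of 1 minus the Pearson correlation of ln levels over the 17578 pairs of the 188 clusters present at all stages, over 6493 genes with a mean level of at least 0.1 at any stage, with a 95% range from 200 bootstrap draws of clusters. A gene was ON at a probability of at least 0.5. A cluster was cholinergic with VAChT or ChAT ON, glutamatergic with VGlut ON, GABAergic with Gad1 or VGAT ON, and aminergic with Vmat, ple, Tdc2 or SerT ON. Factors ON in at least 3 and OFF in at least 3 of the 179 neuronal Adult clusters were tested against each of 3 transmitters with two-sided Fisher's exact tests, 186 in all, with Benjamini-Hochberg adjustment over them. Of 103 factors listed, 62 met that rule. Marker counts took an adjusted p-value under 0.01 and a log fold change of at least 0.5 in the authors' deposited tables. Related clusters were compared by the number of genes apart by at least 1 ln unit. Clusters 234 and 235 were chosen for this by their ON state of acj6, SoxN and Sox102F, the markers fixed for T4 and T5 neurons.

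Genes named in the text are the 12 largest changes each way from P15 to Adult and the 3 largest each way between adjacent stages, leaving out genes known only by an annotation number. Of each list they are the 4 members with the largest difference and any member at least 0.5 ln units against its list. For distinctness they are the 10 genes with the largest fall and the 10 with the largest increase of the SD, for factors the 10 smallest p-values, and for the related pair the 5 largest differences each way at P15 and in the Adult. Transmitter genes were always named. The genes of the clusters that end before the Adult, of the P15-only clusters and of the Osi family were named after their values were seen, as were further list members named at single steps between stages and br from P15 to Adult.

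Alternatives fixed in advance were centring on the median gene, clusters of all 6 stages only, means in place of medians, a linear scale with pseudocounts of 0.1 and 1, other level filters, other thresholds, P30 as the first stage, other distances and gene sets, other probabilities for ON, other factor stages, other marker thresholds, and names compared without case. Neuronal clusters only, clusters with at least 500000 estimated counts and thinning to equal estimated counts were added after the data were seen. Alternatives that need cell type names (biological names only, 1 cluster per related group, L1 to L5) or values per library were not run, and P30 as the first stage does not apply to adjacent steps.

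The calculations were tested on simulated data made from the P15 profile of 10671 genes drawn as a pair of stages. All 50 genes planted higher by 1 ln unit and all 50 planted lower were called, 0 of 100 planted at 0.3 ln units were called, and 0 of 10471 unchanged genes were called. These draws held counting noise at the estimated counts only. They do not show how differences between libraries or in normalization would affect the calls. Of 100 random lists of 20 genes 3 lay below percentile 5 or above percentile 95. In 180 simulated clusters, 10 of 10 planted factors and 0 of 50 unrelated factors passed the adjusted threshold. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Raw reads and values per cell were not used here.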

Results

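Optic lobes of Drosophila melanogaster, the visual part of the fly brain, were profiled by droplet-based single-cell RNA sequencing at 6 stages. The 38 libraries of the Canton S strain comprised 5 from P15, 5 from P30, 4 from P40, 4 from P50, 5 from P70 and 15 from adults aged 1 to 3 days, where the number after P is the percent of pupal development. All pupal libraries and 13 adult libraries were female, and the other 2 adult libraries pooled both sexes. Each stage was read from tables in which the authors had pooled its libraries, with 1 column per cell cluster and between 11099 genes (P40) and 12028 genes (Adult). A cluster number stood for the same cluster at every stage, and 231 clusters appeared in at least 1 table. Levels are given as transcripts per 10000, meaning normalized counts per 10000 counts of a cell, or as natural log (ln) values of 1 plus that level. The libraries were pooled and each table was normalized on its own, so no replicate error could be computed for any difference between stages. A gene was called changed by size alone: a median difference over clusters of at least 0.5 ln units, with at least 90% of clusters moving the same way. The number of counts behind a column was not given and was estimated, on the high side, at medians between 863523 at P40 and 2913120 in the Adult.

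Between P15 and Adult, clusters gained transcripts of synaptic transmission and energy metabolism and lost those of the ribosome and the growing cytoskeleton. The largest rise was that of the long noncoding RNA mimi (listed as CR31451), from 2.05 to 104.7 transcripts per 10000, a median difference of 3.27 ln units over clusters. It was followed by ps, the RNA-binding protein Pasilla (3.07), Hasp (2.82), TM4SF (2.63) and Ald, which encodes the glycolytic enzyme aldolase (2.51). Rdl, a GABA-gated chloride channel subunit, rose from 1.16 to 24.1, and the synapse-associated Sap47 from 4.75 to 50.7. The rises of PyK (2.32), IA-2 (2.30), jdp (2.30), Glut4EF (2.23) and Cbp53E (2.22) completed the 12 largest. On the other side, the actin-binding cib fell from 37.8 to 0.646 transcripts per 10000, by -3.14 ln units, and tsr, the actin-severing cofilin, from 30.4 to 1.08. Df31 (-2.83), hdc (-2.71), the actin gene Act42A (-2.58) and fax (-2.41) fell as well, as did the small heat shock genes Hsp23 (-2.33), Hsp27 (-2.31) and Hsp67Bc (-2.104), the ribosomal protein gene sta (-2.17), HmgD (-2.16) and Akap200 (-2.14).

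In all, 532 genes were higher and 500 were lower in the Adult table among the 10671 genes present at both stages. The median difference over the 4549 genes past the level filter was -0.02. These were 4.99% and 4.69% of genes. On a linear scale with a pseudocount of 0.1 the shares were 10.4% and 11.4%, and with every cluster required to move the same way they were 2.61% and 2.57%.

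Glycolysis stood furthest above other genes among the lists that rose. Of its 12 measured genes 11 were higher in the Adult, led by Ald, PyK, Pglym78 (2.15) and Gapdh2 (1.72), and the list median was 1.25 ln units. Of the 80 nuclear-encoded genes of oxidative phosphorylation, 59 rose and 0 fell, including Cyt-c-p (2.07), ND-B14 (1.26), ND-23 (1.16) and RFeSP (1.16), with a list median of 0.68. Of 17 transcripts of the mitochondrial genome 7 rose, among them mt:lrRNA (1.34), mt:ND4 (0.98), mt:CoI (0.80) and mt:CoIII (0.76). Of the 29 genes of synaptic vesicles and active zones 19 rose and 0 fell. They included cpx, which clamps vesicle fusion (2.08), Snap25 (1.93) and the calcium sensor Syt1 (1.67), and the list median was 0.72. Of 25 ion channel genes 12 rose, with Hk (2.104), the sodium channel para (1.95), NaCP60E (1.86) and the calcium-activated potassium channel slo (1.81) in front. Each of these lists lay at or above percentile 99.9 of 10000 random lists matched on size and level.

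Receptor genes moved less together. Of 12 acetylcholine receptor genes 3 rose, including nAChRbeta1 (1.54) and nAChRalpha3 (0.60), while nAChRalpha6 (0.98) and nAChRalpha7 (0.65) did not move the same way in enough clusters to be called. Among the 17 receptors for glutamate, GABA and histamine, Rdl, GluClalpha (0.64) and GluRIB (0.53) rose and KaiR1D fell (-0.55). Of 14 enzymes and transporters of transmitters 5 rose, led by Ddc (1.27), Gad1 (1.18), VGlut (1.18) and ChAT (0.73). These are medians over all clusters, most of which had the gene OFF: in neuronal clusters with it OFF the median level went from 0.0130 to 2.08 transcripts per 10000 for Gad1 and from 0.495 to 3.56 for VGlut. In the dpr and DIP families of paired recognition molecules dpr1 (0.93), dpr14 (0.86) and dpr18 (0.67) rose, and 29 of the 32 genes were not called. None of the 21 beat and side genes passed the rule, and beat-IIIb (0.64), side (0.59), beat-IIa (0.52) and beat-VII (0.48) had the largest differences. Of 25 neuropeptide genes Tk (0.63) and Pdf (0.61) rose from a median listed at 0, and Nplp1 (0.45) and sNPF (0.27) did not pass the rule. These too are medians over all clusters, and a gene of this list was ON in a median of 1.5 clusters in the Adult.

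Ribosomal protein genes gave the clearest fall. Of 85 measured, 80 were lower and 0 higher in the Adult, with a list median of -1.29 and sta, RpS5a (-1.89), RpS20 (-1.81) and RpLP1 (-1.80) the lowest. Of the 27 genes of the growth cone cytoskeleton and immature neurons 10 fell, among them tsr, Act42A, the profilin gene chic (-2.08) and betaTub56D (-2.01). In that list futsch, a microtubule-associated protein of axons, rose (1.17), as did bnb (0.67) and trio (0.50), while scrt (0.55) was not called. Among 36 other adhesion genes Lac (-1.73), fz2 (-1.36), Dscam2 (-1.26) and CadN (-0.77) were among the 5 that fell, and Con (0.66) did not pass. Of 25 axon guidance genes only Sema2b fell (-0.52), and Ephrin (-0.44), Fas2 (-0.37) and side (0.59) did not pass. Diap1, an inhibitor of caspases, fell (-1.09), as did the caspase Dcp-1 (-0.67), while hid (-0.49) and Dronc (-0.24) were not called among the 12 cell death genes. In the Wnt list fz2 and arm (-0.82) fell, and Wnt4 (-0.34) and pan (0.32) did not pass.

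Few transcription factors of the fixed list met the rule. Of 89 measured only Pdp1 (1.39), fru (1.23) and Mef2 (0.51) rose, 0 fell, and ct (-0.65) was not called. The list median was 0, which says little: a factor was ON in a median of 7 clusters at P15 and 5 in the Adult, so that clusters with it OFF set the median. Members with a level of at least 0.5 gave -0.07, and a log2 ratio with a pseudocount of 0.1 gave -0.39. In the ecdysone list Hr38 (2.04), ftz-f1 (1.22) and Eip63F-1 (1.06) rose from a median listed at 0, while Eip93F (-0.998) and br (-0.78) fell and 18 of 23 were not called. Of 17 stress and immediate early genes 3 rose, among them Hr38 and the noncoding RNA Hsromega (1.04), while Hsp23 and Hsp27 fell. None of the 18 progenitor and cell cycle genes passed, with E(spl)mgamma-HLH (-0.31), stg (-0.19), geminin (-0.11) and PCNA (-0.10) in front. In the photoreceptor list rdgA (0.76), rdgB (0.68) and norpA (0.63) rose and rdgC (0.31) was not called. Of 11 Kenyon cell genes jdp and Mef2 rose, mub fell (-0.75) and sNPF was not called. Of 8 dosage compensation genes none passed, with Sxl at 0.29, roX1 at 0.11, msl-1 at -0.08 and mle at 0.04.

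**Figure D1:**
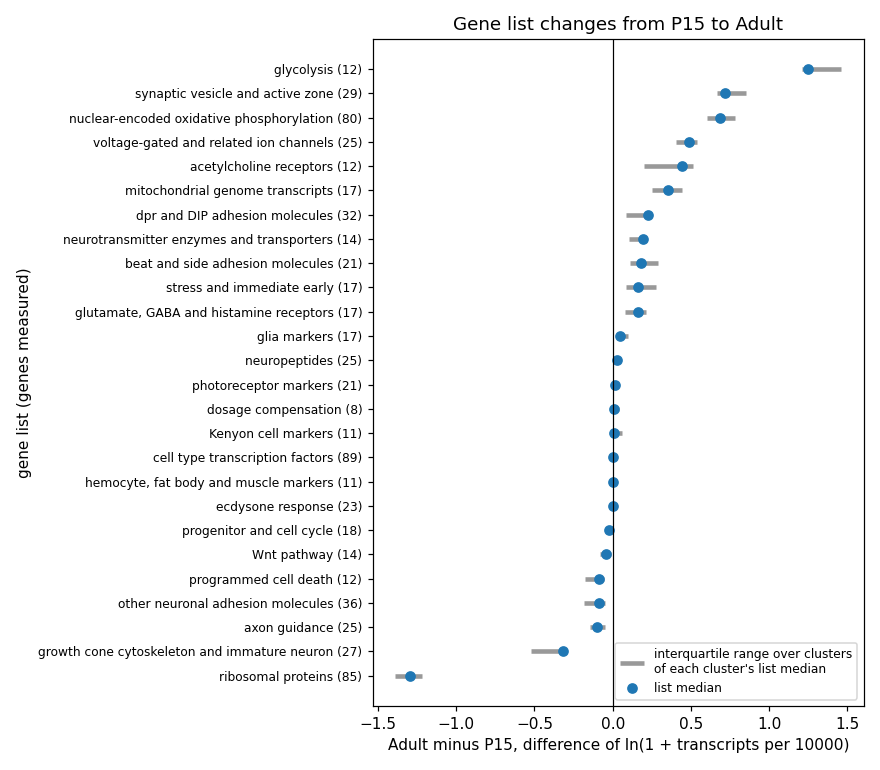
Median difference between the Adult and P15 tables for each fixed gene list, in natural log units of 1 plus transcripts per 10000, with bars for the interquartile range over clusters of each cluster's list median. Glycolysis lies highest at 1.25 and ribosomal proteins lowest at -1.29.

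Between P15 and P30, 23 genes rose and 8 fell. The nuclear receptor Hr4 rose from 0.0459 to 6.71 transcripts per 10000 (1.99 ln units), and Eip74EF, an early ecdysone response factor, from 0.109 to 5.73 (1.81). The gap junction gene shakB rose by 1.40. The largest falls were those of the noncoding RNA CR33938 (-1.05), l(3)neo38 (-0.88) and br (-0.76), a factor induced by ecdysone at the onset of metamorphosis. From P30 to P40, 45 genes rose and 15 fell. Rdl (1.64), the nuclear receptor Hr3 (1.62) and ps (1.48) led the rises, Hr4 went on to 29.95, and hdc (-2.11), Fim (-0.98) and fabp (-0.89) fell most. The ribosomal list had a median of -0.27 in this step.

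From P40 to P50, 4 of 23 ecdysone genes fell, 0 rose and 19 were not called. Eip74EF fell from 10.3 to 1.45 (-1.45), Hr4 by -0.84 and Blimp-1 by -0.89, while 41 genes rose and 18 fell in all. The mitochondrial transcript mt:ND5 rose most (1.33), after having fallen by -0.70 from P30 to P40, with Scp2 (1.07) and Vajk3 (1.05) next, and Osi9 (-1.02) and Hsp27 (-0.91) fell. Transcripts of the mitochondrial genome had a list median of 0.26.

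From P50 to P70, a longer interval than each of the 3 before, 272 genes changed, of which 54.4% were higher. The cuticle-related genes Osi20 (2.31) and Osi15 (2.15) rose from a median listed at 0, with their highest levels (504.8 and 447.5 transcripts per 10000) in a cluster where elav and repo were both OFF, and ftz-f1, a nuclear receptor of the late ecdysone cascade, rose from 0.208 to 8.27 (1.97). Hr4 fell by -1.85, Hsp67Bc by -1.76 and Hsp23 by -1.64. Of 12 glycolysis genes 7 rose, Ald from 1.66 to 12.8 (1.60), and the list median was 0.75. The tubulin genes betaTub56D (-1.53) and alphaTub84B (-1.12) and the actin genes Act42A (-1.05) and Act5C (-1.05) were among the 9 of 27 growth cone genes that fell, and that list had a median of -0.29. Ribosomal proteins had a median of -0.33, with 8 of 84 genes lower. From P70 to Adult 242 genes changed, of which 40.9% were higher. Fas1 (1.61), mimi (1.56) and Hr38 (1.41) rose most, and Osi20 (-2.29), Osi15 (-2.14) and Twdlbeta (-1.86) fell most, all to a median listed at 0. In this step 43 of 84 ribosomal protein genes fell (median -0.51) and RpS14b rose (0.77), glycolysis rose further (median 0.40, with Hex-A at 0.97 and Pgk at 0.94), and the stress list had a median of 0.43 with Hsp68 at 1.04 and Hsp70Bc at 0.67.

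A question raised by the series is how far cell types converge or diverge in expression as they mature. Cluster profiles were closer in the Adult than at P40. The median of 1 minus the Pearson correlation over 17578 pairs of clusters was 0.0842 at P15, 0.0815 at P30, 0.106 at P40, 0.101 at P50, 0.0956 at P70 and 0.0802 in the Adult. The Adult value was 0.758 times that at P40, with a 95% bootstrap range over clusters of 0.726 to 0.788, and 87.96% of pairs were closer in the Adult. The P15 value was 0.796 times that at P40, with a range of 0.763 to 0.829. The ranges of the Adult (0.0750 to 0.0856) and P30 (0.0769 to 0.0855) overlap, and P30 was lowest after thinning to equal estimated counts (0.0852 against 0.0862 in the Adult) and in clusters with at least 500000 estimated counts (0.0729 against 0.0795). P15 was lowest with the 1000 most variable genes (0.117 against 0.158) and at a mean level of at least 0.5 (0.0960 against 0.102). Over 1727 genes that were ON in 3 to 20 clusters at both stages, the level in OFF clusters was a median 24.2% of that in ON clusters at P40 and 36.1% in the Adult, with median ON levels of 0.690 and 0.502.

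The ratio of Adult to P40 distance differed between gene lists. In the Adult the distance was 0.0139 times the P40 value for progenitor genes (5 genes only), 0.212 times for glia markers, 0.314 times for glycolysis, 0.456 times for oxidative phosphorylation, 0.472 times for acetylcholine receptors, 0.497 times for synaptic genes, 0.562 times for ion channels, 0.659 times for axon guidance, 0.690 times for transcription factors, 0.716 times for other adhesion genes, 0.726 times for the dpr and DIP families and 0.799 times for receptors of glutamate, GABA and histamine. It was close to equal for beat and side genes (0.994). Transmitter enzymes and transporters were at 2.97 times the P40 distance, but their distance of 0.490 in the Adult was below the 0.669 at P15, with 0.165 at P40 and 0.131 at P50. In neuronal clusters with VGlut OFF its median was 0.495 transcripts per 10000 at P15, 3.18 at P40 and 5.33 at P50. Gad1 in ON clusters was at 1.58 at P40, 2.83 at P50 and 31.2 at P70. The glutamatergic share of neuronal clusters was 28.5% at P40 and 28.1% at P50. The low distances at these stages thus do not show a loss of transmitter identity. Ratios above 1 were also found for ecdysone response genes (2.01), ribosomal proteins (1.58), stress genes (1.53), Kenyon cell genes (1.23), neuropeptides (1.14) and growth cone genes (1.05). The spread over clusters, as the SD of ln levels, fell most for the adhesion gene Lac (from 0.82 to 0.30), Npc2b (from 0.62 to 0.17), the noncoding RNA CR45312, NimA, rst, GluRIB, Dtg, Hr4, nAChRalpha7 and olf413. It increased most for Gad1 (from 0.33 to 1.25), Ddc (from 0.07 to 0.90), Dop2R (from 0.32 to 1.11), Proc, Ugt35B1, Spn43Ab, jdp, ChAT, ninaE and Sod3. The mean ln level fell too for Lac (from 2.02 to 0.19), Npc2b (from 1.31 to 0.08) and Hr4 (from 3.43 to 0.01). It changed less for GluRIB (from 1.18 to 1.08) and nAChRalpha7 (from 1.96 to 1.65). The genes with the largest increase all had a higher mean in the Adult, such as Gad1 (from 0.16 to 1.78). Changes of spread were thus not separated from changes of level. Of the 6493 genes, 5142 had a lower SD in the Adult than at P40 and 1351 a higher one. Most of these differences were small. Among genes whose SD differed by at least 0.25, the lower ones outnumbered the higher ones only slightly. Whether the many small falls follow from the higher estimated counts of the Adult columns was not tested. The order of the early stages depended on the genes used: P15 lay above P40 with transcription factors alone (ratio 1.03) and with synaptic, channel and receptor genes alone (1.05).

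**Figure D2:**
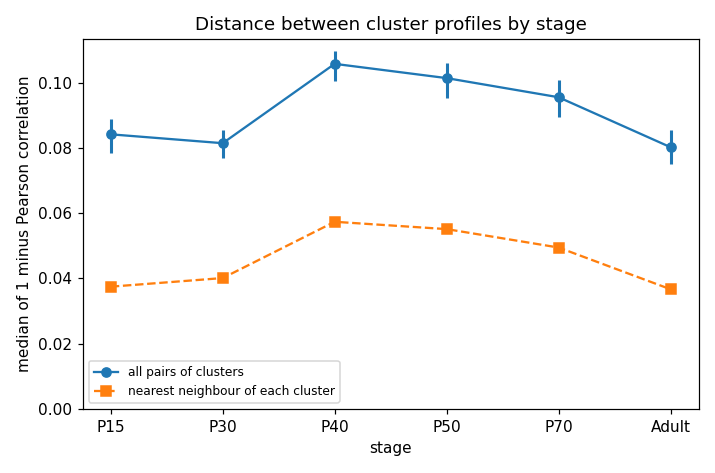
Median distance between cluster profiles at each stage, as 1 minus the Pearson correlation of ln levels, over all pairs of clusters (with 95% bootstrap range over clusters) and over nearest neighbours. Both lines peak at P40, at 0.106 and 0.0574, and end at 0.0802 and 0.0367 in the Adult.

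Some genes of the fast transmitters were ON in similar shares of neuronal clusters at P15 and in the Adult, while VGAT and VAChT were ON in more Adult clusters. By the authors' mixture-model probability, VGlut, the vesicular glutamate transporter, was ON in 28.2% of neuronal clusters at P15 and in 28.5% in the Adult. For Gad1, which makes GABA, the shares were 18.2% at P15, 11.8% at P50 and 20.7% in the Adult. VGAT, the vesicular GABA transporter, was ON in 7.18% at P15 and 20.1% in the Adult. Its ON call separated clusters less well at P15. The median VGAT level in OFF clusters was 42.2% of that in ON clusters at P15 and 13.2% in the Adult. The difference between its P15 and Adult shares is therefore uncertain. ChAT, which makes acetylcholine, and the vesicular transporter VAChT were ON in 44.2% and 38.1% at P15 and in 46.9% and 51.4% in the Adult. The choline transporter ChT was ON in 40.9% and 43.6%. For VAChT the OFF median was 7.85% of the ON median at P15 and 9.96% in the Adult. ChAT and VAChT start at the same base of chromosome 3R (18705501 in BDGP6.54), and reads from the part they share cannot be told apart.

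Levels in the clusters that had each gene ON differed between stages as well. The median VGlut level was 13.4 transcripts per 10000 at P15, 56.98 at P40 and 63.6 in the Adult. Gad1 stood at 1.88 at P15, 1.58 at P40 and 2.83 at P50, then at 31.2 at P70 and 72.01 in the Adult. ChAT went from 0.809 to 5.50 and VAChT from 0.831 to 3.92 between P15 and Adult, with most of the difference after P50. These levels come from separately normalized tables.

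**Figure D3:**
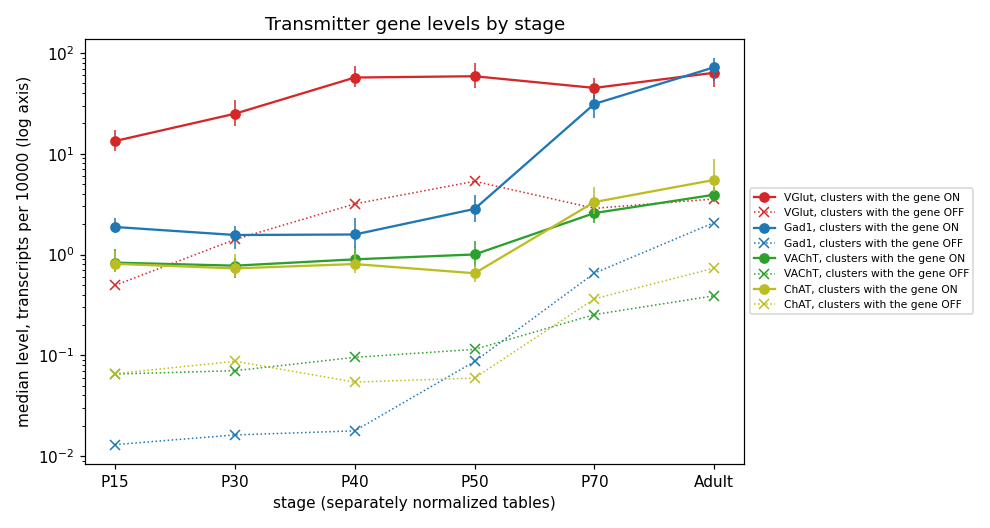
Median level of transmitter genes at each stage, in transcripts per 10000 on a log axis, over neuronal clusters with the gene ON (solid) and OFF (dotted). Gad1 in ON clusters went from 2.83 at P50 to 72.01 in the Adult.

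Counted by identity, 49.7% of neuronal clusters were cholinergic at P15 and 51.4% in the Adult, 28.2% and 28.5% were glutamatergic, and 19.9% and 20.7% were GABAergic. Clusters with none of the fast or aminergic identities numbered 8 at P15, 10 at P40 and 2 in the Adult, and those with more than 1 fast identity numbered 5, 9 and 3. Among clusters neuronal at both P15 and Adult, 0 differed in glutamatergic identity, 4 in GABAergic and 9 in cholinergic identity. In cholinergic identity 10 clusters differed from the Adult at P40 and 10, mostly others, at P50, and in GABAergic identity 6 differed at P40 and 8 at P50. With a mean level of at least 0.5 ln units in place of the probability, the glutamatergic share of all clusters was 99.5% in the Adult, where neuronal clusters with VGlut OFF had a median of 3.56 transcripts per 10000.

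Most monoamine genes were ON in few clusters, while Ddc and Tbh were ON in more. Vmat, the vesicular monoamine transporter, was ON in 2 neuronal clusters at every stage and ple, which makes the precursor of dopamine, in 1 or 2. In cluster 31 the Adult levels were 97.3 for Vmat, 42.5 for ple and 19.7 for the dopamine transporter DAT. The serotonin genes Trh (7.33) and SerT (1.87) were highest in cluster 85, and Tdc2, which makes tyramine, was ON in 1 Adult cluster at 1.73. Tbh was ON in 18 neuronal clusters in the Adult at a median of 0.479, and Hdc, which makes histamine, in 0. The highest Adult level of Hdc, 0.651, was in cluster 3, a neuronal cluster with none of the transmitter identities. Ddc was ON in 1 neuronal cluster at P15, 28 at P70 and 67 in the Adult, where its median level in them was 11.5. The highest Adult level of Ddc (117.7) was in a cluster with the glial factor repo ON. In neuronal clusters with Ddc OFF its median level was 0.0239 at P15 and 1.41 in the Adult.

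Several transcription factors were associated with a transmitter across Adult neuronal clusters. The LIM-homeodomain factor ap went with the cholinergic identity: 90.8% of clusters with ap ON were cholinergic against 22.3% of those with it OFF (Fisher's exact test, p = 2.94e-21, Benjamini-Hochberg adjusted p = 5.47e-19). Lim3, another factor of that class, went with GABA, at 65.3% against 3.85% (Fisher's exact test, adjusted p = 5.87e-16), and away from the cholinergic identity (16.3% against 64.6%, Fisher's exact test, adjusted p = 1.28e-07). None of the 88 clusters with scro ON was GABAergic, against 40.7% of the others (Fisher's exact test, adjusted p = 1.06e-11), and 73.9% of them were cholinergic (adjusted p = 1.03e-07, Fisher's exact test). Of the 38 clusters with the SoxD factor Sox102F ON 37 were cholinergic (Fisher's exact test, adjusted p = 2.80e-10), and none of the 76 clusters with ap ON was GABAergic (Fisher's exact test, adjusted p = 1.74e-09). Of the 17 clusters with the homeodomain factor hth ON 14 were GABAergic (Fisher's exact test, adjusted p = 2.39e-07). Clusters with the Pax6 gene toy ON were glutamatergic in 4.55% of cases against 42.5% (Fisher's exact test, adjusted p = 1.49e-07). None of the 22 clusters with the nuclear receptor svp ON was cholinergic, against 58.6% of the others (Fisher's exact test, adjusted p = 5.00e-07).

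Of the factor and transmitter pairs tested over 62 factors, 57 passed an adjusted p of 0.05, 31 as more frequent and 26 as less frequent together. They involved 32 factors and were 28 cholinergic, 19 glutamatergic and 10 GABAergic pairs. The test was two-sided, and related clusters are not independent, so these p-values describe association over these clusters only.

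The pair of clusters that had acj6, SoxN and Sox102F ON at every stage, the marker set fixed for the motion-detecting T4 and T5 neurons, are called T4/T5-like here (clusters 234 and 235). In the Adult 1 further cluster, listed only at P70 and in the Adult, also had all 3 genes ON and was not compared. At P15 cluster 234 had more Lar, a receptor phosphatase of axon targeting (42.8 against 8.14 transcripts per 10000), the noncoding RNA CR44978 (difference 1.68 ln units), Mip (1.33), beat-IIIb (1.28) and the adhesion gene Fas2 (1.24). Cluster 235 had more of the T-box factor bi (11.5 against 0.829), mav (24.7 against 6.08), pros (5.63 against 1.18), klg (2.93 against 0.336) and kmr (2.499 against 0.285). In the Adult beat-IIIb (18.8 against 5.23) and Fas2 (4.12 against 0.690) were still higher in cluster 234, with Ptp99A (difference 1.21), CG15537 (0.79) and sano (0.48). The adhesion gene klg (22 against 2.32), Con (7.31 against 1.87), bi (2.09 against 0.409), robo2 (2.96 against 0.9004) and pros (2.76 against 0.986) were higher in cluster 235.

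By a difference of at least 1 ln unit, genes that differed between the 2 clusters were most frequent at P40. The number of genes apart was 10 at P15, 10 at P30, 23 at P40, 20 at P50, 6 at P70 and 5 in the Adult. Their distance as 1 minus the correlation was 0.0202 at P40, 0.0206 at P50 and 0.00437 in the Adult. At a difference of at least 2 ln units the share of genes was also higher at P50 (0.0259%) than at P40 (0.0180%). Those shares came from very few genes, Fas2, Ptp99A and klg at P50, and do not settle the order of these stages. Genes ON in one and OFF in the other were 0.451% at P15, 0.670% at P30, 1.0001% at P40, 0.777% at P50, 0.661% at P70 and 0.374% in the Adult.

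The number of marker genes per cluster was highest at P70. In the authors' deposited table of markers per stage, the median number per cluster with an adjusted p under 0.01 and a log fold change of at least 0.5 was 63.5 at P15, 69 at P30, 80 at P40, 86 at P50, 96 at P70 and 69 in the Adult. In the authors' deposited table for P15, dpr9 (2.13), Lim1 (1.95) and Drgx (1.74) had the largest log fold changes in cluster 234, and mav (2.41) had the largest in cluster 235. Those p-values treat cells as units. At a log fold change of at least 1 the median at P70 was 23, below the 26 at P50.

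Some clusters were present only early. At P15, 18 clusters (numbers 240 to 257) stood in no other table, and 1 cluster (233) was listed at P15 and P30 only. Of the 13 clusters listed at P70 and not in the Adult, 9 were listed from P15 on, among them clusters 223 and 224, the only ones of the 13 that were neuronal by the rule used here. The secreted ligand Wnt4 was the mark of cluster 223, at 563 transcripts per 10000 at P15, 772 at P40 and 348 at P70, against a median of 0.701 in other neuronal clusters at P15. Wnt10 was highest in cluster 224, at 57.5 at P15, 49.6 at P50 and 43.5 at P70, and cluster 228 had 12.3, 46.7 and 6.49. Cluster 233 had 442 for Wnt4 at P15 and 333 at P30. In the authors' deposited table for P15, the log fold change was 4.76 for Wnt4 in cluster 223, 3.85 for Wnt10 in cluster 224 and 4.19 for Wnt4 in cluster 233.

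Death genes were high in both Wnt clusters at P70. The level of skl, an antagonist of caspase inhibitors, was 18.5 in cluster 223 and 45 in cluster 224, against a median of 0.0661 in other neuronal clusters. The related rpr stood at 1.78 and 5.35 against 0.0392, and grim at 0.957 and 2.71 against 0.00729. These were the highest values of any cluster at that stage for all 3 genes. In the other 11 clusters that were not listed in the Adult skl was at most 0.131. The fourth gene of the family, hid, was at 0.166 and 0.425 against 0.159. At P50 skl was already highest in the same clusters, at 1.47 and 0.922, while at P15 it ranked 91 and 53 among all clusters. The mean level of 17 stress and immediate early genes was also high in them at P70, at percentiles 98.3 and 100 of neuronal clusters. At P50 that mean lay at percentiles 60.5 and 94.9. Hsp23 was at 5.34 and 14.4 at P70, against a median of 2.54.

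**Figure D4:**
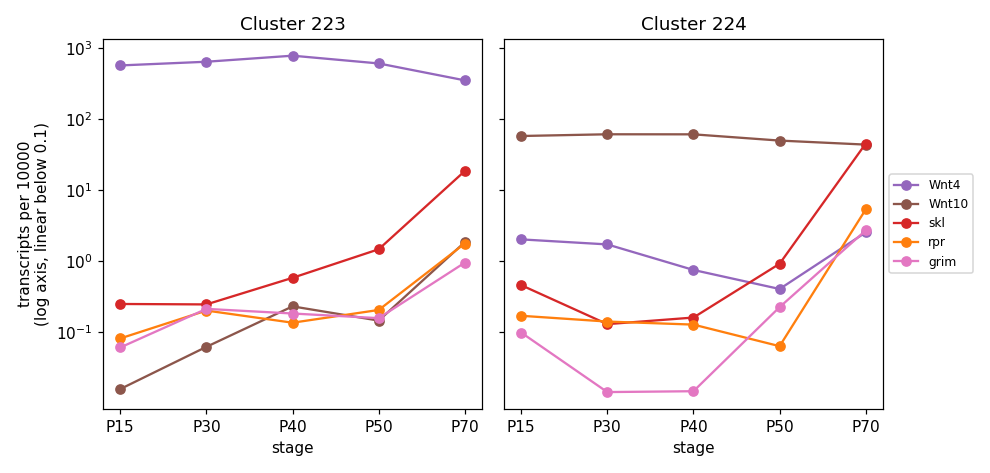
Levels of Wnt and death genes in clusters 223 and 224 at each pupal stage, in transcripts per 10000 on an axis that is linear below 0.1 and logarithmic above. The skl level went from 1.47 at P50 to 18.5 at P70 in cluster 223, and from 0.922 to 45 in cluster 224.

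Genes of other cell types were followed in neuronal clusters. The glial glutamate transporter Eaat1 had a neuronal median of 0.139 transcripts per 10000 at P15 and 2.53 in the Adult, where the highest level (301.5) was that of cluster 1, itself neuronal by the rule used here. Gs2, glutamine synthetase of glia, rose from 0.0194 to 7.51 over the clusters in both tables, and nrv2 (1.57) and Gat (1.15) rose too, while Obp44a fell (-0.56) from a neuronal median of 18.2. As a percent of the highest cluster the median over glial genes in neurons was 0.373 at P15 and 1.36 in the Adult. Rhodopsin ninaE, the photoreceptor opsin, had a neuronal median of 0 up to P50, 1.06 at P70 and 0.269 in the Adult, where cluster 3 had 773. Of the hemocyte, fat body and muscle genes Pxn (0.10), Col4a1 (0.07), vkg (0.02) and wupA (0.01) had the largest differences, and none passed. The male-specific RNA roX1 had a neuronal median of 0 at each pupal stage and 0.135 in the Adult, whose libraries included both sexes. Glial and photoreceptor genes thus moved beside the energy and synaptic lists between P15 and Adult, and the pooled tables allow no check by library.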

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

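The comparison of the P15-only clusters with the lasting clusters was chosen after the tables were seen, with gene lists fixed earlier. The 18 clusters listed only at P15 entered no comparison between stages, and death or progenitor genes stood out in some of them. A value is given here where it lay above that of every cluster present at all stages and above the floor of 3 estimated counts. All values are transcripts per 10000 at P15.

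Cluster 252 was high in 3 of the 12 death genes. Its level was 45.4 for skl, against at most 5.09 in a lasting cluster, 19.3 for rpr against 4.37, and 12.1 for grim against 1.94, while hid was at 0.699, below the lasting median of 0.791. The neuroblast factor wor stood at 0.642 there against 0.3496. In the authors' deposited table for P15, skl (log fold change 3.52), rpr (2.76) and grim (2.29) led this cluster.

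Cluster 256 had 17 progenitor and cell cycle genes above all lasting clusters. The neuroblast genes mira (19.9 against 0.816), dpn (8.37 against 0.537), wor (4.095), ase (2.64) and insc (0.218) were among them. Genes of DNA replication were high as well: PCNA at 9.12 against 2.57, CycE at 4.75 against 1.56, Mcm7 at 3.32, Mcm5 at 3.11, Mcm2 at 2.84, geminin at 2.55 and dup at 1.89. Mitotic genes followed, with aurB at 4.63, Cdk1 at 4.36, CycB at 3.05, CycA at 2.82 and polo at 2.35. The death gene grim stood at 7.72.

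Cluster 253 had 13 such genes at mostly lower levels. Mitotic genes led, with Cdk1 at 3.97, aurB at 3.82, CycB at 2.98, polo at 2.32 and CycA at 1.81. Neuroblast genes followed, with wor at 2.97, mira at 2.01, ase at 1.44, dpn at 1.09 and insc at 0.5998, and replication genes were Mcm7 at 0.971, Mcm5 at 0.815 and Mcm2 at 0.7801. Outside the death and progenitor lists, elav was at 14.4 in cluster 253, against at most 11.06 in a lasting cluster and 3.80 in cluster 256. Hey was at 4.96 in cluster 253, against at most 0.857 in a lasting cluster and 0.0952 in cluster 256. In cluster 257 dpn was at 2.76, mira at 1.404, aurB at 1.18 and polo at 1.05. In cluster 254 only ase passed, at 1.03, and in the authors' deposited table for P15 that cluster was marked by esg (1.91), Hey (1.76) and sna (1.74). The other 13 clusters had no gene of either list above the lasting clusters.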

How the results depend on the processing

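Neuronal clusters only, clusters with at least 500000 estimated counts and thinning were chosen after the results were seen, as was the limit of 0.25 for the list medians of single steps tried under other settings. Of the values recomputed for the main comparisons 383 stayed within their spread or within 1.5 times, 5 turned their direction and the others, given below, moved further. Of values for single genes 28 moved. No list median from P15 to Adult changed its sign under any setting run, apart from those listed at 0. No paired analysis was possible because the tables pool the libraries of a stage. Alternatives that need cell type names (biological names only, 1 cluster per related group, L1 to L5), the leaving out of single libraries, and P30 as the first stage of adjacent steps were not run. Depth limits low genes most: estimated counts per column had medians of 863523 at P40 and 2913120 in the Adult. Where a cause is not named below, the cause was not tested.

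For the lists from P15 to Adult, the log2 ratio of back-transformed means is another unit (log2 in place of ln, a smaller pseudocount), which by itself raises sizes. With a pseudocount of 0.1 it gave 2.60 for glycolysis, 1.95 for synaptic genes, 1.89 for channels, 1.56 for transmitter enzymes and transporters, 1.53 for photoreceptor markers, 1.33 for oxidative phosphorylation, 1.04 for neuropeptides, 0.90 for glutamate, GABA and histamine receptors, 0.80 for dpr and DIP genes, 0.77 for the mitochondrial genome, 0.66 for glia markers and 0.65 for stress genes. It gave -0.92 for cell death, -0.81 for the growth cone list, -0.77 for axon guidance, -0.73 for other adhesion genes, -0.62 for the Wnt pathway, -0.60 for progenitors and -0.39 for transcription factors, and 1.61 for glycolysis from P50 to P70. With a pseudocount of 1 it gave 0.74 for transmitter enzymes and transporters, 0.26 for neuropeptides, -0.31 for axon guidance, -0.30 for other adhesion genes and -0.0768 for transcription factors. With list members of a level of at least 0.5 only, which leaves fewer genes, the medians were 1.05 for glia markers, 0.73 for transmitter enzymes and transporters, 0.67 for the mitochondrial genome, 0.63 for photoreceptor markers, 0.45 for stress genes, 0.45 for neuropeptides, 0.39 for dpr and DIP genes, 0.31 for glutamate, GABA and histamine receptors, 0.29 for dosage compensation, 0.0716 for Kenyon cell markers and 0.0375 for the ecdysone list. They were -0.67 for cell death, -0.57 for the growth cone list, -0.31 for the Wnt pathway, -0.26 for other adhesion genes, -0.26 for axon guidance and -0.0707 for transcription factors. With P30 as the first stage acetylcholine receptors had 0.17 and Kenyon cell markers 0.0694. As means over clusters, neuropeptides had 0.0757 and transcription factors -0.0240. Centred on the median gene, transcription factors and hemocyte, fat body and muscle markers each had 0.0219.

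Of genes changed from P15 to Adult, a threshold of 1 left 1.61% higher and 1.42% lower, every cluster in one direction 2.61% and 2.57%, and the linear scale gave 10.4% and 11.4%.

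For distinctness, ratios to P40 are given. With Spearman correlations they were 0.929 for P15, 0.818 for P30, 0.993 for P50 and 0.620 for the Adult. With the Euclidean distance they were 0.891 for P15, 0.876 for P30, 0.940 for P70 and 0.847 for the Adult. With the 1000 most variable genes they were 0.673 for P15, 0.735 for P30, 0.999 for P50, 1.02 for P70 (turned) and 0.907 for the Adult. With transcription factors alone they were 1.03 for P15 (turned), 0.906 for P30, 0.910 for P50 and 0.690 for the Adult. With adhesion and guidance genes they were 0.975 for P15, 0.910 for P30 and 0.859 for the Adult. With synaptic, channel and receptor genes they were 1.05 for P15 and 1.08 for P30 (both turned), 0.801 for P50, 0.632 for P70 and 0.477 for the Adult. Without ribosomal, mitochondrial, stress and photoreceptor genes they were 0.844 for P15, 0.813 for P30, 0.863 for P70 and 0.697 for the Adult. Over nearest neighbours they were 0.653 for P15, 0.699 for P30, 0.862 for P70 and 0.639 for the Adult. At a mean level of at least 0.5 they were 0.732 for P15 and 0.754 for P30. In clusters with at least 500000 estimated counts they were 1.0012 for P50 (turned), 0.953 for P70 and 0.836 for the Adult. After thinning they were 0.792 for P30 and 0.801 for the Adult. The Adult stayed below P40 in every one of these settings.

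With a mean level of at least 0.5 ln units in place of the probability, VGlut was ON in 46.8% of clusters at P15, so that this share was glutamatergic, and in 99.5% in the Adult, and Gad1 in 100% in the Adult. The glutamatergic share was 96.5% at P30, 100% at P40 and P50 and 99.5% at P70 and in the Adult. The GABAergic share was 87.9% at P70 and 100% in the Adult, the cholinergic share 84.9% in the Adult, and 3.98% of neuronal clusters had the same identities at P15 and in the Adult. Factor and transmitter pairs past an adjusted p of 0.05 numbered 377 with all genes tested, where 40 of the 57 listed pairs stayed. Of those pairs 54 stayed at a probability of 0.8, 45 with P50 factors and 44 with P15 factors.

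For markers in the authors' deposited table, a log fold change of at least 1 gave medians of 20.5 at P15, 21 at P30, 25 at P40, 26 at P50, 23 at P70 and 17 in the Adult. The curated form of the authors' deposited table gave 3 at P15, 3 at P30, 4 at P40, 3 at P50, 4 at P70 and 3 in the Adult. For the T4/T5-like pair, a difference of 0.5 took in 0.195% of genes at P15, 0.287% at P30, 0.640% at P40, 0.631% at P50, 0.258% at P70 and 0.0831% in the Adult. A difference of 2 left 0% at P15, 0.0174% at P30, 0.0180% at P40, 0.0259% at P50, 0.00858% at P70 and 0% in the Adult. Genes ON in one and OFF in the other were 0.451% at P15, 0.670% at P30, 1.0001% at P40, 0.777% at P50, 0.661% at P70 and 0.374% in the Adult.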

Other observations

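The patterns weighed below had been seen before their tests, and the thinning of clusters, the comparison of shares for the Osi genes, the control for their correlation, the other clusters that end at P70 and the stress means at P50 and in other clusters were chosen after the data were seen. The Wnt clusters shared more than their ligands. The peptide hormone gene Capa was highest in clusters 223 and 224 at P50, at 73.8 and 45.1 transcripts per 10000 against a median of 0.0388 in other neuronal clusters, and at P30 it reached 58.4 in cluster 233. At P70 the T-box factor bi stood at 37.8 in cluster 223 and 45.04 in cluster 224 against a median of 0.510 in other neuronal clusters, though cluster 231 had 40.2. The proteoglycan dally, which binds Wnt ligands, was at 47.5 and 32.2 against 2.77, and wls, needed to secrete Wnt ligands, at 4.49 and 4.81 against 0.506. The Wnt receptor gene fz2 differed between them, at 5.08 and 113.6. At P50 and P70 neither cluster had any of the transmitter identities, though at P15, P30 and P40 both had at least 1.

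Combinations of transcription factors stayed of similar size at every stage. In the fixed list a median of 10 factors was ON per cluster at P15 and in the Adult, and 9 at P50 and P70. A factor was ON in a median of 7 clusters at P15 and 5 in the Adult. In the T4/T5-like pair the difference of cluster 234 minus 235 was -1.08 for klg at P15 and -1.94 in the Adult, while that of bi was -1.92 and -0.79.

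Clusters were less distinct in the Adult table than at P40. More counting noise at P40, of the size that the estimated counts imply, is argued against. Each cluster was thinned to the same estimated counts in both tables. Over 20 draws, 84.9% of the difference was left (range 84.4 to 85.3). Those estimates lie on the high side, so thinning may add too little noise, and a larger effect of counting noise is not excluded. Free RNA shared by all clusters in the Adult cannot be told apart from the pattern: over 1727 genes the OFF level was 24.2% of the ON level at P40 and 36.1% in the Adult. That ratio of 1.49 (95% bootstrap range 1.45 to 1.55) spans the bound of 1.5 set for it, and it came mostly from the median ON level, 0.690 at P40 and 0.502 in the Adult, while the median OFF level was 0.144 and 0.152. Maturation of the neurons, which the stages name, stays open and untested, since each stage was a table of its own.

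Osi20 and Osi15 were higher across clusters at P70 than at P50 or in the Adult. For most neuronal clusters, expression by some of the neurons themselves is argued against. Their summed Osi level differed by a ratio of only 1.84 between the 90th and the 10th percentile of clusters (35.6 and 19.3). That ratio cannot show expression limited to clusters outside these percentiles. Free RNA from the pair of clusters with the highest Osi level cannot be told apart by the test set for it: over 256 other genes highest in that pair, the Spearman correlation between their level there and in neurons was 0.821, but genes highest in other clusters gave at least as much in 48 of 68 clusters. Neurons held a median of 0.259% of the pair's level for these genes, against 1.83% for the summed Osi genes. The members of the pair differed in this. Free RNA from the one with the higher Osi sum is a candidate source: of its genes at 5 transcripts per 10000 or more, neurons held a median of 1.94% for 34 other genes (range 1.25% to 3.53%) and 1.80% for 5 Osi genes, a ratio of 1.08. With no minimum level the medians were 1.14% and 1.73%. For the other member the medians were 0.685% and 0.252% at that minimum. Among the genes highest in that member, apn was the most abundant (429.1) and stood at 1.21 in neurons (0.283%). Low expression by all neurons alike was not tested and stays open.

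Clusters 223 and 224 carried death gene RNA at P70 and have no column in the Adult table. The other 11 clusters that end at P70, none of them neuronal by the rule used here, had at most 0.131 of skl, so absence also occurred without it. That the same cells form an Adult cluster of their own under another number is argued against. Their best correlations with any Adult cluster were 0.843 and 0.850. These lay below the 5th percentile of 0.880 that lasting neuronal clusters had with their own Adult column. Cells of clusters 223 and 224 that had merged into a larger Adult cluster might not reach that bound either. General stress or damage of the cells is not excluded: their mean level of 17 stress and immediate early genes lay at percentiles 98.3 and 100 of neuronal clusters. Hsp23 was at 5.34 and 14.4 against a median of 2.54. Some values go less well with it. At P50 cluster 223 already had the highest skl with its stress mean at percentile 60.5 (94.9 in cluster 224), and at P70 clusters 68 and 86 had higher stress means than cluster 223 with skl at 0 and 0.324. Developmental death of these neurons after P70 may be a further explanation, which was not tested and stays open beside stress.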
